A study of Homo sapiens with 10 samples.

How the data were processed

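RNA was measured by sequencing in 10 libraries from 2 human leukaemia cell lines. Kasumi-1 had 3 control and 3 JOA libraries, and NB4 had 2 control and 2 JOA libraries. Treatment lasted 48 hours, with JOA at 1 µM, per the labels. Total RNA was extracted with Trizol and libraries were made with a TruSeq stranded mRNA kit, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks, HTSeq and the build hg38, with no versions and no roles. The source label of the NB4 treated libraries names I13, while their titles, agent and treatment labels name JOA, and they were grouped as JOA.

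The authors deposited 1 table per cell line. The Kasumi-1 table holds FPKM values, per the deposited file's name, in 29053 rows labelled with sequence records. Of these rows, 10906 (37.5%), holding 45.8% of the summed FPKM, were matched to 10802 gene symbols. Only 1634 matched with the same record version, 1529 rows carried a repeated label, 87 symbols lay on more than 1 row, and 3 rows with no record were left out. Among 6664 rows with low values, 6613 (99.2%) held whole multiples of 1 step per library, within a tolerance of 0.01 of a read, which put the depth of the 6 libraries at 91.4 to 100% of that of control 1. The NB4 table is also named for FPKM, but each deposited column sums to just under 1000000, so its values were taken as TPM. It lists 121005 transcripts, of which 93.9% were matched to GENCODE and summed to 21972 genes, and the unmatched transcripts held 3.04% of the TPM. The design fixed before the data were examined had assumed FPKM for NB4, and the same log-scale test was applied to its TPM values. TPM keeps no depth, so the depth of NB4 is unknown. No counting interval was computed for Kasumi-1.

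Each line was fitted with limma 3.58.1 (R 4.3.3, with Python 3.11.15 for reading the tables) on log2(value + 1), with a variance trend, no replicate block, and genes at 1 or more in at least as many libraries as the smaller group has. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. A fold change on the log2(value + 1) scale understates the change of genes at low level. The response of the lines was compared as the difference of differences in 1 fit over all 10 libraries, on genes with a symbol in both tables that passed the filter in at least 1. Shared calls were counted with a 2-sided Fisher's exact test. A set of 37 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 where 5 or more members were tested, and again with an estimated correlation. Coordinates come from the GENCODE annotation on GRCh38.

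Control and JOA libraries carry the same replicate numbers. In Kasumi-1 the deviations of same-numbered libraries from their group means correlated at 0.329, 0.499 and 0.423, and those of all other pairs at -0.06 or below, so the numbers were taken as pairs and a fit with the number as a block is given beside the unpaired one. The pairing comes from these values and not from a label. Replicates correlated at 0.978 to 0.986 and shared at most 0.11% of identical values. Nothing states that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

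The rule for named genes, fixed before the data were examined, took a set of 16 genes whatever their result, of which 1 is not reported here, and in each line the 10 largest rises and 10 largest falls among calls whose groups do not overlap and whose higher group has a mean of at least 5. It also took up to 4 members per list that stood out, and 5 genes per side of the difference between lines. Because the unpaired fits called 0 genes in Kasumi-1 and 1 in NB4, the rule was applied to the paired calls in Kasumi-1 and to calls from a fit with variance shared over both lines in NB4. Both fits were alternatives planned in advance, but using them to name genes was decided after those counts were seen. For the difference between the lines, the genes are given from the same shared fit.

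The fits were tested on simulated data with 200 changed genes and variances drawn from the prior that limma fitted. Unpaired Kasumi-1 (11751 rows) recovered 59.7% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes, with 1 false call among 169. Paired Kasumi-1 (11724 rows) recovered 89.6%, 98.5% and 100%, with 8 false among 200. NB4 (12694 rows) recovered 10.4%, 71.6% and 100%, with 10 false among 131. The changed genes had a mean of at least 5, and the noise was independent between genes. The 990 paired calls in the real Kasumi-1 data had a median log2 change of 0.32 in size, against 0.59 fitted for the simulated 1.5-fold changes. The shares recovered and false thus do not carry over to changes of that size or to genes that move together. An earlier simulation took limma's posterior variances as the true ones and gave 28 false among 228 calls for paired Kasumi-1 and 17 among 187 for NB4. It was replaced after its output was seen, because posterior variances are already shrunk: its refitted prior degrees of freedom were 6.66 and 2112, against 3.40 and 5.59 in the real fits, while the later version gave 3.14 and 4.84. The fit over both lines was simulated on 5768 genes that passed the filter in each line, with 2-fold changes in NB4 alone. When each line had its own variance, the difference test recovered 87% with 21 false among 195 calls, and NB4 calls held 59 false among 249. With variances truly shared these counts were 10 of 184 and 7 of 194 (5767 genes). The median residual SD was 0.115 in Kasumi-1 and 0.141 in NB4, so the former case is the nearer one.

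Alternatives planned in advance were other pseudocounts, filters and scalings, no variance trend, shared variance, the replicate block and leaving out each library. Added after seeing the data were the same settings within the paired fit, removal of each library's trend with GC content and length (splines with 4 degrees of freedom), with its mean or keeping it, list tests of the difference between the lines, and median-ratio scaling of the shared-variance fit and of the agreement between the lines. No value column was left unused.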

Results

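The data are transcript levels in 2 human myeloid leukaemia cell lines after 48 hours with 1 µM JOA or a control treatment. Kasumi-1, a line with the RUNX1-RUNX1T1 fusion, had 3 libraries per group, with FPKM values that sum to 265821 to 277628 per library and relative depths of 91.4 to 100%. NB4, an acute promyelocytic line with the PML-RARA fusion, had 2 libraries per group, with TPM values and unknown depth. Values are means ± SD over these libraries, and the tables were normalised separately, so levels are not compared between lines. The series compares each line with and without JOA.

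Kasumi-1 cells held more EGR1 and NQO1 and less HLA-DRA with JOA when libraries were compared in pairs, while the unpaired test called no single gene. Without pairing, as fixed before the data were examined, limma called 0 of 12130 genes (lowest adjusted p = 0.115). At an unadjusted p under 0.05 there were 1986, of which 1420 were higher and 566 lower with JOA, and with median-ratio scaling 1957, of which 1022 were higher and 935 lower. With same-numbered libraries as pairs, 990 passed, 741 up and 249 down. Among them EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), rose from 2.23 ± 0.610 to 6.22 ± 1.96 FPKM, a log2 change of 1.14 (SE 0.09, paired adjusted p = 0.0260). NQO1, a quinone reductase induced by oxidative stress, rose from 2.69 ± 0.740 to 6.31 ± 1.56 FPKM (log2 change 0.99, paired adjusted p = 0.0278). HLA-DRA, an MHC class II chain, fell from 18.3 ± 3.65 to 9.36 ± 0.992 FPKM (log2 change -0.89, paired adjusted p = 0.0232). Each of these moved in the same direction in 3 of 3 pairs, which the naming rule requires, since it admits only genes whose groups do not overlap.

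Other genes named by rule that rose in the paired test were RGCC, from 5.10 ± 0.174 to 10.6 ± 3.11 FPKM, the nuclear long RNA NEAT1, from 5.61 ± 1.91 to 10.4 ± 3.36 FPKM, and the ETS factor ETV5, from 3.87 ± 1.40 to 7.26 ± 1.69 FPKM. HOMER3 rose from 8.65 ± 1.73 to 15.1 ± 4.31 FPKM, PAQR6 from 2.93 ± 0.158 to 5.44 ± 0.750 FPKM and RFLNB from 11.6 ± 1.52 to 19.2 ± 0.731 FPKM. The microRNA loci MIR6739 and MIR3176 each had a log2 change of 0.80. Since they lie on the same strand within IPO9 and CAPN15, their reads cannot be told from those of the host genes. Genes that fell included PHPT1, from 31.8 ± 3.36 to 19.6 ± 0.375 FPKM, and the growth factor MDK, from 36.1 ± 4.01 to 23.8 ± 5.01 FPKM. Lower too were TXNIP, an inhibitor of thioredoxin, from 56.3 ± 11.7 to 39.3 ± 9.47 FPKM, and TNFSF13B, from 25.3 ± 2.68 to 17.5 ± 1.02 FPKM. COPS9, HMGN5, TENT5A, the RNA polymerase subunit POLR2L and ATP23 fell by smaller amounts, with log2 changes from -0.49 for COPS9 to -0.38 for ATP23.

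**Figure D1:**
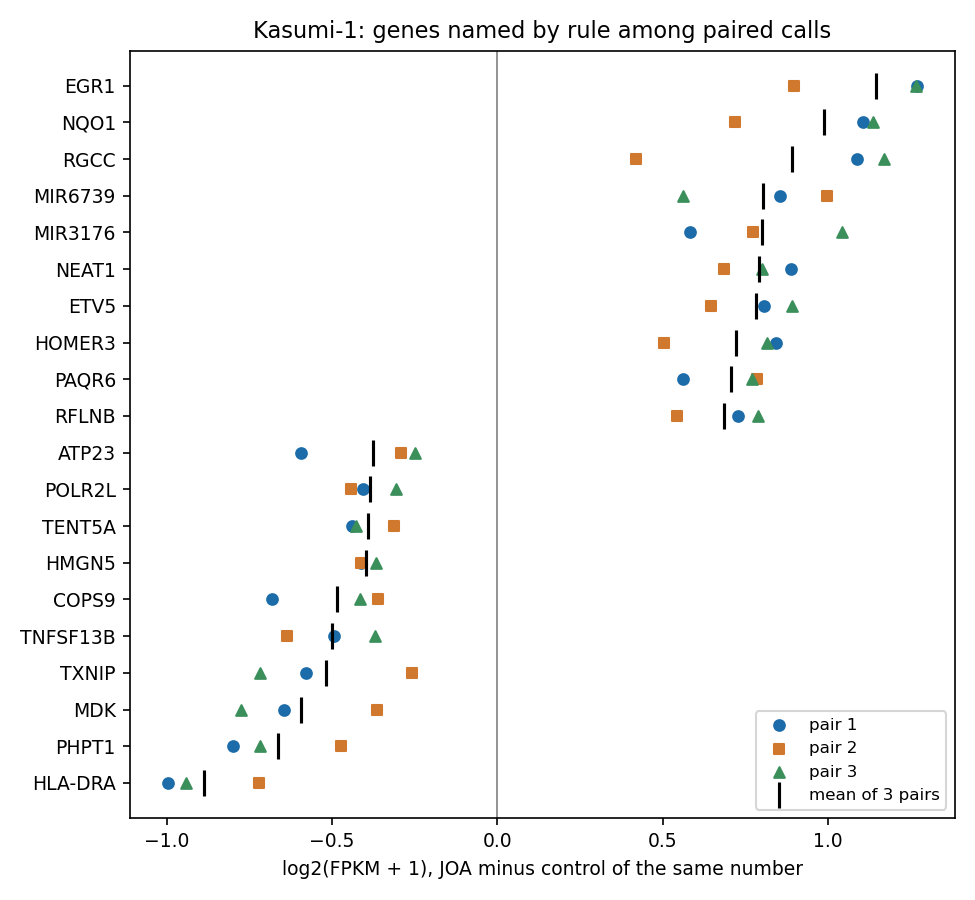
Log2(FPKM + 1) of each Kasumi-1 JOA library minus the control library of the same number, for the 20 genes named by rule among the paired calls; each marker is 1 of 3 pairs and the bar is their mean. EGR1 had a mean of 1.14 and HLA-DRA of -0.89. The 3 pairs of each gene lie on 1 side of 0, which the rule requires, since it admits only genes whose groups do not overlap.

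NRF2 target genes, which serve antioxidant defence, rose as a list in Kasumi-1 in the paired test (camera adjusted p = 0.00511, and adjusted p = 0.749 with an estimated correlation). Of 15 tested, 6 rose over all genes (NQO1, PIR, BLVRB, FTH1, GCLM and PGD) and 9 when adjusted over the list alone. PIR went from 3.00 ± 0.401 to 4.79 ± 1.39 FPKM and PGD from 150.5 ± 2.15 to 184 ± 6.17 FPKM. Lysosome and autophagy genes also rose (camera adjusted p = 0.00273, and adjusted p = 0.675 with an estimated correlation), with 6 of 16 up over all genes and 7 adjusted over the list alone. SQSTM1, an autophagy receptor, went from 7.50 ± 0.498 to 12.4 ± 0.837 FPKM, and TFE3, a lysosomal transcription factor, from 4.99 ± 0.185 to 8.31 ± 1.06 FPKM. Among myeloid transcription factors (camera adjusted p = 0.0308, and adjusted p = 0.749 with an estimated correlation), 4 of 7 rose over all genes and 4 adjusted over the list alone: EGR1, CEBPB (from 4.17 ± 0.260 to 6.72 ± 0.887 FPKM), TFEC and KLF6.

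Genes of MYC-driven nucleolar ribosome biogenesis fell as a list in Kasumi-1 (camera adjusted p = 8.09e-08, and adjusted p = 0.675 with an estimated correlation). Of 24 tested, 4 fell over all genes (MYBBP1A, RRS1, UTP20 and RRP1B) and 13 adjusted over the list alone, while MYC itself stood at 297 ± 20.4 to 297 ± 9.66 FPKM (paired adjusted p = 0.981). Cholesterol synthesis fell (camera adjusted p = 6.45e-04, and adjusted p = 0.675 with an estimated correlation), with HMGCS1, MSMO1, TMEM97 and FDFT1 down and STARD4 up over all genes, and 6 down and 1 up adjusted over the list alone, of 15. ER chaperones fell (camera adjusted p = 0.0307, and adjusted p = 0.749 with an estimated correlation), with HSPA5, CALR and PDIA6 down of 14 over all genes, and 5 down and 1 up adjusted over the list alone. In the heat shock list (camera adjusted p = 0.0151, and adjusted p = 0.675 with an estimated correlation), HSP90AB1 and STIP1 fell and BAG3 rose of 15 over all genes, and 4 fell and 2 rose adjusted over the list alone. DNA replication genes (camera adjusted p = 0.0163, and adjusted p = 0.849 with an estimated correlation) had 1 of 34 down by both counts, MCM7, and ribosomal proteins (camera adjusted p = 3.92e-04, and adjusted p = 0.749 with an estimated correlation) had RPS23 down of 11 by both counts. Oxidative phosphorylation genes (camera adjusted p = 0.0483, and adjusted p = 0.749 with an estimated correlation) had 0 of 12 past either count in limma. The 36 mitosis genes had a median of 0.01 and did not pass (camera adjusted p = 0.238, and adjusted p = 0.849 with an estimated correlation).

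Of the 10 lists called in the paired Kasumi-1 test, 0 passed with an estimated correlation, and primary granule genes passed unpaired and not paired (camera adjusted p = 0.0968, and adjusted p = 0.749 with an estimated correlation). Leaving out any 1 pair brought the paired gene calls in limma from 990 to 0, where 3781 genes were at an unadjusted p under 0.05 with all pairs. Under 3 other scalings of the paired values no called list changed direction, but replication, ER chaperone, heat shock, cholesterol and ribosomal protein lists kept their call under 2 of 3, and oxidative phosphorylation under 1. The share of risers among them, 74.8%, was 52.3% with median-ratio scaling, 61.3% with quantile scaling and, among genes with a symbol, 71.3% with the trend with GC content and length removed and 42.3% with each library's mean removed too. Unpaired list calls went from 11 to 7 without control 2 and to 6 without control 3. Of the paired calls, 440 have no gene symbol and were in no list.

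KIT, a receptor tyrosine kinase, stood at 244 ± 70.8 to 229 ± 73.9 FPKM (paired adjusted p = 0.166), MPO at 5762 ± 366 to 5481 ± 325 FPKM, RUNX1 at 37.3 ± 1.02 to 40.3 ± 2.03 FPKM and RUNX1T1 at 18.8 ± 0.822 to 18.6 ± 1.55 FPKM. None of these passed in Kasumi-1. CEBPA, SPI1, E2F1, CDKN1A and RARA did not pass either. ITGAM and CD86 lay under the filter, and CD14, CD34 and PML were not analysed here in Kasumi-1 because no value carried their symbol.

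In NB4, the interferon-induced chemokine CXCL10 (chromosome 4, 76021117 to 76023497) fell from 8.69 ± 0.594 to 0.404 ± 0.255 TPM, a log2 change of -2.80 (SE 0.24, limma adjusted p = 0.0476), with both JOA libraries below both controls. The interferon response list did not fall with it (camera adjusted p = 0.764, and adjusted p = 0.975 with an estimated correlation). Of its 40 tested genes 32 were positive, with a median of 0.17, against 0.09 with median-ratio scaling. CXCL10 was the 1 call among 12949 genes, with 1375 at an unadjusted p under 0.05, of which 1061 were higher and 314 lower. With median-ratio scaling there were 1208 at that threshold, 617 higher and 591 lower. Leaving out any 1 of the 4 libraries brought the count to 0, as did median-ratio scaling and a pseudocount of 0.1. Among 7260 genes fitted with variance shared over both lines, 156 passed, 122 up and 34 down. Only 76 of the up and 16 of the down calls also passed the filter in Kasumi-1. The others lay under it there, where a small spread can lower the shared SE, as for VIT from 0.192 to 0.116. Simulated data of 5768 genes past the filter in each line, 200 of them changed 2-fold in NB4 alone, gave 59 false among 249 NB4 calls with a variance per line. That simulation does not cover genes under the filter in Kasumi-1. With median-ratio scaling 84 passed the shared fit, 45 up and 39 down, and 77 of the 156 kept their call.

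In that shared fit NB4 cells had higher TRIB2, a pseudokinase (from 8.19 ± 0.114 to 17.8 ± 1.26 TPM, shared adjusted p = 0.00553), and NEDD4, a ubiquitin ligase (from 13.8 ± 0.0845 to 29.3 ± 1.76 TPM, shared adjusted p = 0.00221). So were LGALS3, galectin-3 (from 7.94 ± 0.0958 to 17.1 ± 2.09 TPM), the inflammasome sensor NLRP1 (from 4.89 ± 1.53 to 11.2 ± 0.673 TPM), and ALOX5AP, which serves leukotriene synthesis (from 2.94 ± 1.25 to 7.20 ± 1.55 TPM). FGF6, H2BC5, CCDC146 and TMEM187 were also higher. EIF3CL was higher too, but it has a near copy, EIF3C, so its value is uncertain. Lower were VIT (from 8.36 ± 0.659 to 3.46 ± 0.391 TPM) and the potassium channel KCNH2 (from 54.1 ± 9.38 to 26.5 ± 11 TPM). RGS16, RBPMS, ZNF417 and DNAH17 were lower as well, with the sterol genes DHCR7 and INSIG1, and the ER gene SDF2L1. The integrin ITGAM, a myeloid differentiation marker fixed in advance, went from 14.2 ± 2.06 to 21.7 ± 2.11 TPM (adjusted p = 0.305 within NB4, 0.0474 in the shared fit). It lay under the filter in Kasumi-1, and its SE was 0.161 within NB4 and 0.132 in the shared fit. With median-ratio scaling ITGAM, ALOX5AP, H2BC5 and DHCR7 did not pass the shared fit (adjusted p of 0.0516 to 0.104). MPO went from 7838 ± 205 to 5282 ± 853 TPM (adjusted p = 0.276) and MYC from 569 ± 7.93 to 484 ± 37.2 TPM (adjusted p = 0.468). Neither passed within NB4, nor did CEBPA, SPI1, RUNX1, RARA, PML, E2F1, CDKN1A or CD86. CD14, CD34, KIT and RUNX1T1 lay under the filter.

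Mitosis genes rose as a list in NB4 (camera adjusted p = 2.69e-11, and adjusted p = 0.441 with an estimated correlation), and all 45 tested had a positive change, with a median of 0.30. For comparison, the median of all tested NB4 genes was 0.085, and 69.0% of the 5768 genes tested in both lines were positive in NB4. Of the 45 mitosis genes, 0 passed over all genes in limma, and 15 passed adjusted over the list alone. HMMR went from 28.6 ± 2.47 to 41.8 ± 0.250 TPM and TOP2A, the topoisomerase of dividing cells, from 89.7 ± 11.9 to 126 ± 10.8 TPM. DNA replication genes fell as a list (camera adjusted p = 6.89e-12, and adjusted p = 0.441 with an estimated correlation), with 43 of 50 negative, a median of -0.14, and 0 past over all genes or adjusted over the list alone in limma.

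**Figure D2:**
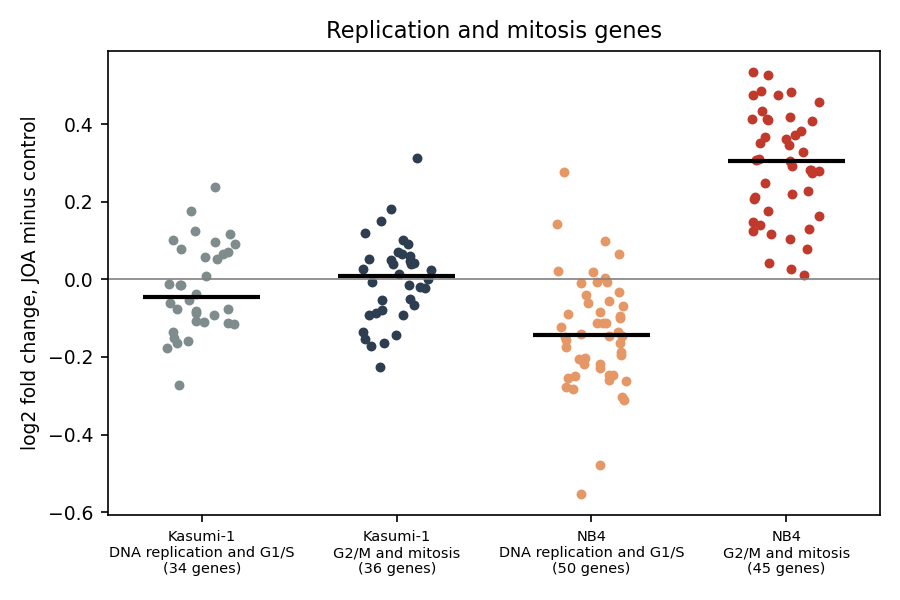
Log2 fold change, JOA minus control, of each replication and mitosis gene tested in each line; each point is a gene and the bar is the median. In NB4 the medians are -0.14 for replication and 0.30 for mitosis, against -0.05 and 0.01 in Kasumi-1.

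Primary granule genes, which mark promyelocytes, fell in NB4 (camera adjusted p = 3.28e-11, and adjusted p = 0.441 with an estimated correlation). Of 18 tested, 15 were negative, 0 passed over all genes in limma, and 8 fell and 1 rose (NKG7) adjusted over the list alone. PRTN3 went from 199 ± 81.9 to 41.5 ± 0.613 TPM and CTSG from 366 ± 42.7 to 169 ± 69.2 TPM. Cholesterol synthesis fell (camera adjusted p = 1.81e-11, and adjusted p = 0.575 with an estimated correlation), with 4 of 25 down adjusted over the list alone and 0 over all genes. HMGCS1 went from 84.2 ± 28.9 to 40.4 ± 4.57 TPM. ER chaperones fell (camera adjusted p = 1.81e-11, and adjusted p = 0.441 with an estimated correlation), with 5 of 27 down adjusted over the list alone and 0 over all genes. CALR went from 2173 ± 319 to 1286 ± 126 TPM. Metallothioneins fell (camera adjusted p = 6.27e-07, and adjusted p = 0.441 with an estimated correlation), with 4 of 6 down adjusted over the list alone and 0 over all genes. MT2A went from 318 ± 23.7 to 193 ± 21 TPM. NF-kB and inflammatory genes fell (camera adjusted p = 7.81e-08, and adjusted p = 0.441 with an estimated correlation), with CCL3 and CXCL8 down adjusted over the list alone and 0 of 22 over all genes. CCL3 went from 5.45 ± 0.0659 to 1.20 ± 0.0304 TPM.

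Phagocyte oxidase genes, which make the respiratory burst, rose in NB4 (camera adjusted p = 0.0128, and adjusted p = 0.441 with an estimated correlation), with NCF4, CYBB, HVCN1 and RAC2 up of 7 adjusted over the list alone and 0 over all genes. CYBB went from 43.3 ± 0.139 to 61.8 ± 13.9 TPM. Epithelial and fibroblast markers rose (camera adjusted p = 0.0326, and adjusted p = 0.441 with an estimated correlation) with 5 of 6 positive, KRT8 and KRT18 up adjusted over the list alone and 0 over all genes. KRT18 went from 20.8 ± 2.00 to 30.5 ± 1.48 TPM. Ribosomal proteins rose (camera adjusted p = 0.0133, and adjusted p = 0.818 with an estimated correlation), with 52 of 60 positive, and kept their call under 2 of 3 other scalings. Their median went from 0.13 to 0.03 with median-ratio scaling, where the call was lost (camera adjusted p = 0.282). Ribosome biogenesis (camera adjusted p = 7.23e-08, and adjusted p = 0.441 with an estimated correlation), glycolysis (camera adjusted p = 1.59e-07, and adjusted p = 0.441 with an estimated correlation) and oxidative phosphorylation (camera adjusted p = 4.17e-05, and adjusted p = 0.633 with an estimated correlation) fell as lists. In these and the ribosomal proteins 0 members passed in limma over all genes or adjusted over the list alone. Mitochondrially encoded transcripts fell (camera adjusted p = 1.51e-08, and adjusted p = 0.530 with an estimated correlation), 12 of 13 negative and 0 past either count in limma. They held 15.5 ± 1.29% of TPM in control and 12.2 ± 1.38% in JOA libraries (n = 2 each), a shift that moves with each of these lists. None of the 14 lists called in NB4 passed with an estimated correlation.

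**Figure D3:**
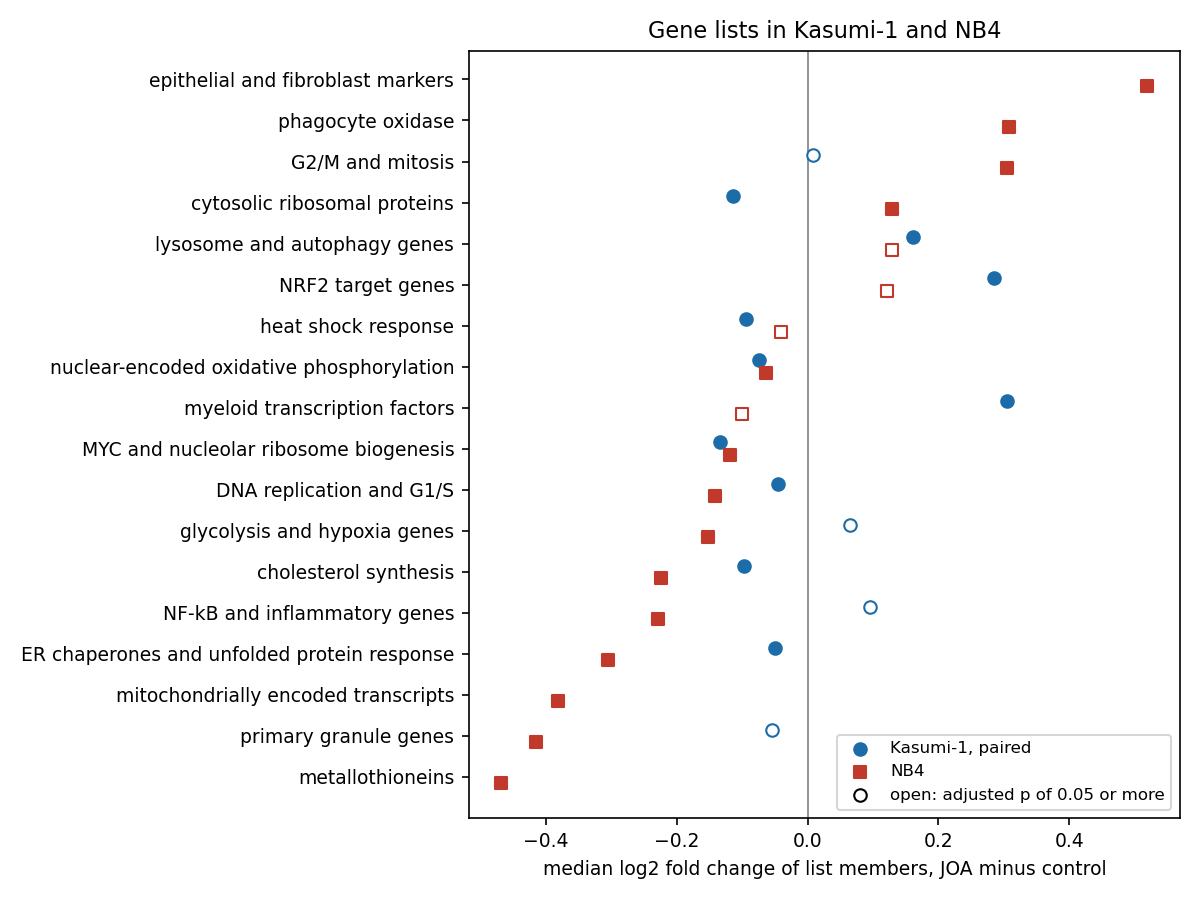
Median log2 fold change, JOA minus control, of each list called in either line, with Kasumi-1 from the paired fit and NB4 unpaired; filled markers had a camera adjusted p under 0.05 at the preset correlation. Metallothioneins in NB4 had a median of -0.47 and NRF2 target genes in Kasumi-1 of 0.29.

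The difference between the lines was tested on 7260 genes, and 14 passed, 6 with a higher and 8 with a lower change in Kasumi-1 than in NB4, with 846 at an unadjusted p under 0.05. CXCL10 differed by 2.80 on the log2 scale (adjusted p = 4.17e-05), but its mean in Kasumi-1 was 0.0340 FPKM. The chemokine CXCL8 had a log2 change of 1.06 in Kasumi-1 and -1.11 in NB4 (difference adjusted p = 0.0394). The Fc receptor chain FCER1G had log2 changes of -0.58 and 1.00 (difference adjusted p = 0.0125), and ACY3 of -0.31 and 0.81 (difference adjusted p = 0.0187). Of the 14 genes, 7 had a mean under 1 in at least 1 line, SDK2 in both (0.210 FPKM and 0.961 TPM). With a pseudocount of 0.1 the count fell to 2. The pseudocount and the filter at 1 were applied to FPKM in Kasumi-1, summing to 265821 to 277628 per library, and to TPM in NB4. Since the NB4 columns sum to just under 1000000, both weigh more in Kasumi-1 on a gene at the same share. With both lines rescaled to 1000000 per library the count was also 2. Leaving out Kasumi-1 control 1, 2 or 3 gave 2, 4 or 5 calls, and leaving out Kasumi-1 JOA 1, 2 or 3 gave 3, 9 or 4. Without NB4 control 1 or 2 there were 100 or 25, and without NB4 JOA 1 or 2 there were 43 or 19. With the replicate block the count was 36, and all 14 were among them. Of 28 lists, 9 differed between the lines and 0 with an estimated correlation (lowest adjusted p = 0.0947 with an estimated correlation).

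Both lines moved partly alike across genes. No gene passed in both with limma's unpaired fits. Fisher's exact test takes genes as independent, which genes that move together are not, so its p-values below may overstate the evidence. At an unadjusted p under 0.05, 105 of 5768 genes were higher in both lines against 53.2 for independent lists (Fisher's exact p = 8.98e-13), and 20 were lower in both against 5.97 (Fisher's exact p = 1.35e-06). Higher in Kasumi-1 and lower in NB4 were 8 against 13 (Fisher's exact p = 0.178), and the reverse were 8 against 24.4 (Fisher's exact p = 0.00012). With median-ratio scaling, 45 of 5763 were higher in both against 18.0 (Fisher's exact p = 4.11e-09) and 48 lower in both against 21.2 (Fisher's exact p = 3.42e-08). Among paired Kasumi-1 calls and shared-variance NB4 calls, 12 of 6074 rose in both against 4.68 (Fisher's exact p = 0.00213), among them the lysosomal genes TFE3 and WIPI1, the leukocyte genes BIN2 and CD53, and UBA7, which activates ISG15. CALR and POLR2L fell in both, 2 against 0.377 (Fisher's exact p = 0.0532), and ACY3 moved in opposite directions. With median-ratio scaling 3 rose in both (BIN2, CD53 and TFE3) against 0.968 (Fisher's exact p = 0.0704) and 5 fell in both against 0.867 (Fisher's exact p = 0.00131). Across genes, which are not independent replicates, fold changes correlated at r = 0.218 and rho = 0.219, with 60.7% of the same sign against 54.3% for independent signs, since most changes were positive in each line. With median-ratio scaling r was 0.223 and rho 0.224, with 57.1% of the same sign, where 49.8% of changes in Kasumi-1 and 50.7% in NB4 were positive.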

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

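The tests of scaling and of GC content on Kasumi-1, of RNA composition in NB4, and 3 of the 4 tests of low level on the difference between the lines, were chosen only after the result was seen; the other tests were written before.

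A difference between the lines put 14 genes here. On the log2 scale, the change in Kasumi-1 minus that in NB4 was CXCL10 2.80, GPAT3 -1.63, FCER1G -1.58, SDK2 1.65, ACY3 -1.12, VIT 1.08, CCDC146 -1.10, TRIB2 -1.07, DNAH17 1.04, ELN -1.13, CXCL8 2.17, NECTIN1 0.96, NPL -0.99 and ARL6IP5 -0.63, each past the test of the difference. In the test written before, 1 of the 7 genes at 1 or more in both lines kept its call with a pseudocount of 0.1, the outcome named in advance for a low level in 1 line as the cause. But the difference, examined after that outcome, grew in 7 of these 7 (median size 1.07 to 1.17) and its SE with it (median 0.16 to 0.23), and ARL6IP5, at means of 31.5 FPKM and 30.3 TPM, went from an adjusted p of 0.0458 to 0.0849 with a difference of -0.63 and then -0.65. With the smaller pseudocount the difference also grew in 7 of 7 genes under 1 in a line (median size 1.13 to 1.78), so growth cannot tell these cases apart. The outcome named in advance was met, but ARL6IP5 lost its call without a low level, so lost calls alone do not decide. The 7 genes under 1 in a line were all under 1 in the line with the smaller change, and SDK2 in the other line too, which decides nothing. After those outcomes further tests were added. Of the 14 genes, 5 (ACY3, ARL6IP5, CXCL8, ELN and FCER1G) moved by over 2 standard errors in opposite directions, but genes chosen for a large difference favour this. In Kasumi-1 these had an adjusted p of 0.10 to 0.30 unpaired, while ACY3, ARL6IP5 and CXCL8 passed when paired. Of these ACY3 alone passed in both lines (adjusted p = 0.0482 and 0.0117), at a mean of 1.29 TPM in NB4, and 1.79 genes falling in Kasumi-1 and rising in NB4 were expected for independent calls, so this decides nothing for the set. The 9 others all lay under a mean of 5 in the line with the smaller change, which decides nothing either. A low level in 1 line is thus neither established nor excluded. The pseudocount of 1 also weighs more on FPKM in Kasumi-1 than on TPM in NB4, so the test does not put both lines on the same scale. Simulated false calls (21 among 195) come from genes past the filter in each line, so they do not cover the 7 genes under 1 in a line. A different response of the lines stays open as a biological explanation.

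In Kasumi-1, paired calls rose more often than they fell, 74.8% of 990. With median-ratio scaling the share was 52.3%, but median ratios centre the changes, which by itself evens the share, so this decides nothing on scaling as the source. Among rows with a symbol, tested on their own, it was 69.1%, and 42.3% with the trend with GC content and length and each library's mean removed, which centres the changes. After that outcome the test was changed to keep each library's mean, and the share was 71.3%. Keeping the means also keeps the general shift that sets the share (median log2 change 0.041 before and 0.044 after). The share thus does not come from the part of the trend around those means, and no more is decided on that trend as the source. As to the calls themselves, 81.9% of those with a symbol kept their call with trend and means removed, 293 of 391 risers and 151 of 151 fallers. With library means kept it was 94.5%, 368 of the risers and 144 of the fallers. Changes in Kasumi-1 did go with GC content (rho = 0.288), but these shares argue against the trend as the cause of most of these calls. Under median-ratio scaling, quantile scaling and rescaling to 1000000 per library, 100% of the 990 kept their direction and at least 0.51 of their change. Median ratios moved all genes by only 0.039 on the log2 scale, so for calls of this size that outcome was likely from the start. It shows only that these scalings shift values too little to make the changes. This criterion replaced earlier ones, on calls kept, after their outcomes were seen. The calls were less stable: 75.1%, 45.8% and 0% stayed past the threshold in limma (3781 at unadjusted p under 0.05 as deposited). The median size of the 990 changes was 0.32 as deposited and 0.31, 0.28 and 0.35 under the 3, with a median SE of 0.05, 0.05, 0.05 and 0.06, while the median adjusted p went from 0.0378 to 0.0395, 0.0530 and 0.0654. The median adjusted p thus lay near the threshold as deposited, while the lowest was 0.0232 in limma. Rescaling also brought 16122 rows in place of 12130 past the filter. Why the calls ended was not tested.

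In Kasumi-1 without pairing, 10 of the 10 splits of the 6 libraries gave as many genes, since the real one gave 0 and the highest other 3, and 1 of 10 gave as many lists, 11 against 6. Of the 4 splits that part every pair, the real one gave 990 and the highest other 0 (1 of 4). These splits are too few for a share under 0.05.

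In NB4 mitosis genes rose and replication genes fell as lists, with a gap between the medians of 0.45, but 0 of 45 and 0 of 50 passed over all genes in limma (1375 of 12949 at unadjusted p under 0.05), and neither list passed with an estimated correlation (adjusted p = 0.441). The gap was 0.45 with the trend with GC content and length removed, and between 0.39 and 0.48 with 1 library left out, which argues against that trend or a single library as the cause. With median-ratio scaling the medians were 0.21 for mitosis and -0.24 for replication, and with 1 library left out the former stayed at 0.15 or above and the latter at -0.20 or below. Median ratios moved all genes by only 0.085 on the log2 scale, too little to bring either median to 0, so that outcome was set from the start. The test was also written after these medians were seen, so it decides nothing on a shift in RNA composition. A rescaling of all other genes alike, as from the fall of mitochondrial transcripts, could not by itself make the gap, and other effects of composition were not tested. A change in how cells are spread over the cycle stays open and was not tested.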

How the results depend on the processing

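The paired gene and list settings, the removal of the trend with GC content and length, and median-ratio scaling of the shared-variance calls and of the genes moving alike in both lines were chosen after seeing the data. In Kasumi-1, unpaired calls stayed at 0 in limma (1986 at unadjusted p under 0.05) under the settings tried, except 4 with variance shared over both lines, 990 with the replicate block, and 0 to 1 with 1 library left out (1 without JOA 2). Paired calls, 990, went to 0 with no low-value filter, with values rescaled to 1000000 per library and with no variance trend, to 504 with quantile scaling and to 31 at a log2 change of 1 or more, and to 0 with any 1 pair left out (0 to 0), where 3781 were at unadjusted p under 0.05 with all pairs. They were 951 and 928 with pseudocounts of 0.1 and 0.01, 946 with median ratios (743 of the 990 kept, against 453 with quantiles), and 1475 at a mean of 5 or more. Among rows with a symbol, tested on their own, they were 1350, and 1239 with the trend removed and 1103 with library means removed too. In NB4, the 1 call went to 0 with pseudocounts of 0.1 and 0.01, no filter, rescaling to 1000000 per library, median ratios, quantiles and the trend removed, to 0 with any 1 library left out (0 to 0), and to 5 with no variance trend, 156 with shared variance and 150 with the replicate block, whose numbers do not pair the NB4 samples (correlation 0.067), with limma and 1375 at unadjusted p under 0.05. The 14 genes that differ between the lines went to 2 with a pseudocount of 0.1, 0 at a mean of 5 in both lines (846 at unadjusted p under 0.05 as tested), 2 rescaled to 1000000 per library and 36 with the replicate block, and ranged from 2 to 100 with 1 library left out. Lists called went from 11 in Kasumi-1, 10 paired and 14 in NB4 to 0 with an estimated correlation, and ranged over 6 to 12, 8 to 9 and 14 to 17 with a library or pair left out. The cause was not tested for any of these changes. The overlap of the unpaired limma calls was 0 under the alternatives run, but Kasumi-1 had 0 or 1 calls in each, so this says nothing on stability (105 rose and 20 fell in both at unadjusted p under 0.05). With median-ratio scaling those counts were 45 and 48, the 12 and 2 genes that rose and fell in both among paired and shared-variance calls were 3 and 5, and the 156 shared-variance calls in NB4 were 84. Of the values of single named genes, 93 stayed alike, 81 lost their call and 6 changed sign without a call (CEBPA, MYC and RUNX1T1) in Kasumi-1, and 191 stayed alike, 18 gained, 6 lost and 2 changed sign without a call (SPI1) in NB4. With the replicate block, mitosis genes up in NB4 when adjusted over the list alone went from 15 to 0, primary granule genes down from 8 to 13, ER chaperones down from 5 to 12 and mitochondrial transcripts down from 0 to 8. Tests on read counts were not run because neither table holds counts. In NB4, with unknown depth, genes at low level cannot be given a counting error, and in Kasumi-1 none was computed.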

Other observations

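IGLL1, a B cell gene chosen after its values were seen, was lower with JOA in both lines. In Kasumi-1 it went from 5.70 ± 4.33 to 2.16 ± 2.31 FPKM (log2 change -1.13, paired adjusted p = 0.0232), with libraries of the groups overlapping. In NB4 it went from 3.44 ± 0.275 to 0.470 ± 0.321 TPM (log2 change -1.61, adjusted p = 0.173), which does not pass. B cell markers did not fall with it as a group in NB4, where 5 of 6 tested had a positive change and the median was 0.20, against 0.13 with median-ratio and 0.10 with quantile scaling.

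EGR1 and ETV5, both induced by ERK signalling, rose in Kasumi-1, and higher ERK output is a candidate explanation. The list of other ERK output genes was written after those genes were seen to rise and before it was tested. Of 9 tested, KLF6 and SPRED2 rose, the median log2 change was 0.10, and camera gave p = 0.433 with an estimated correlation in the paired fit, so the question stays open.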
